A study of Homo sapiens and Mus musculus with 20 samples.

How the data were processed

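RNA sequencing libraries of MCF7 (human breast cancer) and B16F10 (mouse melanoma) cells were compared, 20 libraries in 10 groups of 2 and 4 tables. Per the labels, RNA was extracted with TRIzol and libraries were built with VAHTS kits. The wild-type libraries, the libraries labelled TET3 KO or Tet3 KO and the hairpin libraries came from polyadenylated RNA, and the siRNA libraries from total RNA depleted of ribosomal RNA. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.0.6 and aligned with TopHat2 2.1.1 to hg19 or mm10. The deposited tables give gene values in FPKM, as their file names state, and the program that computed FPKM was not given in the sources used here. Each table lists genes by symbol with a transcript identifier and gives no position, so none is reported.

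The unit was checked on the values. Within a gene, the FPKM values of the libraries stood in ratios of whole numbers, which gave whole reads within 0.02 reads. Gene lengths are whole numbers of bases, which gave the read total that each library's FPKM was divided by. That total was 33.4 to 53.6 M reads in MCF7 and 26.7 to 38.9 M reads in B16F10. Whole reads were recovered for 99.99% of 10768 human genes and of 10110 mouse genes with a mean FPKM of at least 0.5, and in simulated data 98.06% of 2110 genes were recovered exactly. All columns were mapped to a sample, with 0 left over.

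Genes with a mean FPKM of at least 0.5 over a table's libraries were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with a mean-variance trend) in R 4.3.3, and a Benjamini-Hochberg adjusted p under 0.05 made a call. The 4 tables were fitted apart, since they were normalised apart, and both reagents of a knockdown table were fitted with all 6 libraries of the table. The 6 comparisons set libraries labelled KO against wild type, each hairpin against shscramble and each siRNA against siNC, and a further contrast tested the difference between the reagents. In the MCF7 table with libraries labelled TET3 KO, limma pooled the spread of all genes at a given expression almost completely (24300 total degrees of freedom). Tables were drawn up and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

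Before the data were examined, 19 gene lists, the tests, the named-gene rule and most alternatives were fixed. The lists are those named in the report, where luminal and pigment lineage genes are 1 list, and mitochondrial genes. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 95 list tests. No mitochondrially encoded gene of the list was among the tested genes, and no mouse histone gene of the list matched a tested symbol, so neither gave a result there.

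Genes named in the text are the 3 TET genes, a fixed interferon panel, the 10 largest rises and 10 largest falls per knockout-labelled comparison, and up to 2 risers and 2 fallers of each list with the smallest p. The largest changes were taken among called genes with a mean FPKM of at least 1 and every library of the group on one side of every control library, without predicted genes, readthroughs and small RNAs. For the knockdown tables the smaller of the changes with the 2 reagents ranked the genes. The 14 symbols higher in all 6 comparisons are named as a complete set. Overlaps were set against independent lists of the same length and against 100 simulations of unchanged groups with shared controls, and overlaps between tables were tested with Fisher's exact test, two-sided.

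On simulated comparisons with known changes, the method recovered 100% of genes at every simulated size in 3 of the 4 comparisons simulated, with 10 or 11 wrong of up to 211 calls. In the MCF7 comparison with libraries labelled TET3 KO it recovered 4.41% of changes of 0.5, 53% of changes of 1 and 100% of changes of 2 on the log2 scale, with 8 wrong of 112 calls, so smaller changes were largely out of reach there.

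The alternatives were a pseudocount of 0.1, no filter on low values, libraries rescaled to equal median ratios over genes with a mean FPKM of at least 5, no mean-variance trend, a replicate block, only the 4 libraries compared, and leaving out each library in turn. Voom on the recovered whole reads, the list tests with a block and all alternatives of the count over the 6 comparisons were added after the data were seen. In the hairpin table libraries of the same replicate number deviated together in all 3 pairs of groups (correlation 0.136 to 0.237), for a reason the labels do not give, so blocked values are printed there where they change a call. With a library left out, limma takes the remaining one to vary like the other groups. Reads were not realigned, since no read files were among the deposited tables.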

Results

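RNA sequencing was available for 20 libraries of 2 tumour cell lines: MCF7, a human oestrogen receptor-positive breast cancer line, and B16F10, a mouse melanoma line. The libraries formed 10 groups of 2 libraries in 4 tables. In MCF7, wild-type cells were set against libraries labelled TET3 KO, and a scrambled hairpin RNA (shscramble) against the hairpins shTET3-1 and shTET3-2. In B16F10, wild-type cells were set against libraries labelled Tet3 KO, and a control siRNA (siNC) against siTet3-1 and siTet3-2. The read total behind each library's FPKM was 33.4 to 38.9 M reads in the MCF7 table with libraries labelled TET3 KO and 45.0 to 53.6 M in the MCF7 hairpin table. In B16F10 it was 26.7 to 29.7 M in the table with libraries labelled Tet3 KO and 35.6 to 38.9 M in the siRNA table. Group values are mean FPKM ± SD (SD, n = 2). A list's median is that of its members' log2 fold changes, and its counts are over all genes tested. Counts adjusted over the list alone are added where they differ. For lists that camera did not call, the members not passing are left out and the counts adjusted over the list alone differed by at most 2 in either direction. Log2 fold changes compare log2(FPKM + 1) values, which understates the change of genes with low FPKM. Whether the 2 libraries of a group came from separate cultures was not stated, so p-values measure only spread between these libraries. With libraries labelled TET3 KO limma pooled the spread between libraries over genes, so a small p there can go with replicates far apart, as for TEX19. The stated question was how TET3 depletion changed the transcriptome, with interferon signalling and escape from immunity as the study's subject.

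TET3 oxidises methylated cytosine in DNA, a step towards demethylation. The wild-type MCF7 libraries held 6.97 and 7.12 FPKM of TET3 and the libraries labelled TET3 KO 9.12 and 8.24 FPKM (log2 fold change 0.27, SE 0.32, limma adjusted p = 0.999). With hairpins, TET3 fell from 8.56 and 8.97 FPKM to 2.68 and 2.67 FPKM with shTET3-1 (log2 fold change -1.41, SE 0.053, limma adjusted p = 2.44e-07) and to 1.57 and 1.58 FPKM with shTET3-2 (log2 fold change -1.92, SE 0.053, limma adjusted p = 2.87e-08). In B16F10, Tet3 was 5.57 and 6.25 FPKM in wild type and 12.8 and 12.7 FPKM in the libraries labelled Tet3 KO, a rise (log2 fold change 0.99, SE 0.060, limma adjusted p = 7.32e-07). The siRNAs lowered Tet3 from 13.01 and 13.5 FPKM to 6.004 and 5.68 FPKM with siTet3-1 (log2 fold change -1.06, SE 0.048, limma adjusted p = 1.55e-07) and to 5.46 and 5.48 FPKM with siTet3-2 (log2 fold change -1.14, SE 0.048, limma adjusted p = 6.52e-08). TET3 mRNA was therefore not lower in the libraries labelled KO of either cell line, and the directions given for those libraries rest on their labels. The nature of the edit was not given, and a single FPKM per gene cannot show a frameshift. The related enzyme TET2 rose from 4.24 ± 0.783 to 10.8 ± 4.76 FPKM in the MCF7 libraries labelled TET3 KO (log2 fold change 1.12, SE 0.32, limma adjusted p = 0.029). That call was lost without the filter on low values (limma adjusted p = 0.502) and without wild-type replicate 1 (0.69), wild-type replicate 2 (0.65) or TET3 KO replicate 1 (0.573). Tet2 rose from 1.295 ± 0.0123 to 3.13 ± 0.0884 FPKM in the B16F10 libraries labelled Tet3 KO (log2 fold change 0.85, SE 0.067, limma adjusted p = 4.15e-06) and fell slightly with siTet3-2 (log2 fold change -0.24, SE 0.061, limma adjusted p = 0.0065). Tet2 did not pass the test with siTet3-1 (0.028, limma adjusted p = 0.711), nor did TET2 with shTET3-1 (0.15, limma adjusted p = 0.051, 0.0402 with a replicate block, 0.033 without the mean-variance trend and 0.00892 with voom) or shTET3-2 (-0.022, limma adjusted p = 0.752). TET1 did not pass in MCF7 (-0.043, limma adjusted p = 0.999) and was under the expression filter in the hairpin table. Tet1 rose in the B16F10 libraries labelled Tet3 KO (0.38, limma adjusted p = 0.00171), did not pass with siTet3-1 (-0.082, limma adjusted p = 0.315) and rose with siTet3-2 (0.17, limma adjusted p = 0.0454). The last call was lost after rescaling (0.099, limma adjusted p = 0.224), with a pseudocount of 0.1 (0.0545) and without the filter on low values (0.0726), siNC replicate 1 (0.127) or 2 (0.117) or siTet3-2 replicate 1 (0.183) or 2 (0.0754).

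**Figure D1:**
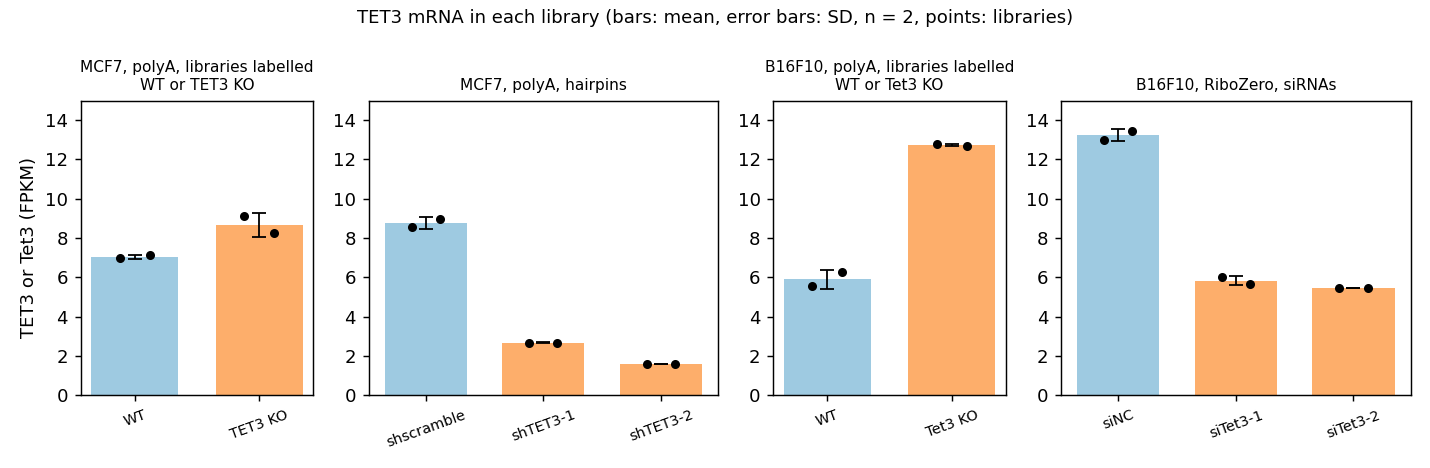
TET3 (MCF7) and Tet3 (B16F10) mRNA in FPKM, with a point for each of the 20 libraries and a bar at each group mean. Both hairpins and both siRNAs lie under their controls, while the libraries labelled KO lie above their wild-type libraries.

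In the MCF7 libraries labelled TET3 KO, IFI27, ISG15 and IFI6 stood highest among the risers. IFI27, a small mitochondrial protein induced by type I interferon, rose from 3.78 ± 0.203 to 117 ± 6.49 FPKM (log2 fold change 4.62, SE 0.32, limma adjusted p = 4.94e-44). The ubiquitin-like modifier ISG15 rose from 18.8 ± 7.29 to 209 ± 7.05 FPKM (log2 fold change 3.46, SE 0.31, limma adjusted p = 3.42e-25), and IFI6, which inhibits viral replication at the endoplasmic reticulum, rose from 41.7 ± 14.3 to 374 ± 57.5 FPKM (log2 fold change 3.17, SE 0.31, limma adjusted p = 9.71e-22). IFIT1, which binds foreign RNA ends, rose from 1.28 ± 0.149 to 12 ± 3.76 FPKM (log2 fold change 2.48, SE 0.30, limma adjusted p = 4.74e-13), and OAS1, which activates RNA decay on sensing double-stranded RNA, rose from 3.78 ± 1.15 to 22.6 ± 2.15 FPKM (log2 fold change 2.32, SE 0.32, limma adjusted p = 3.42e-10). Other large rises were the amino acid transporter SLC6A14 (2.49), the potassium channel KCNJ8 (2.31), the epidermal growth factor receptor ligand AREG (2.31), the antiviral factor SAMD9 (1.98) and OAS3 (1.83), with limma adjusted p between 2.11e-12 and 3.65e-06. The largest falls included SMIM22, a small membrane protein of epithelia (14.4 ± 4.805 to 0.7697 ± 0.457 FPKM; log2 fold change -3.11, SE 0.30, limma adjusted p = 1.42e-21), and TEX19, a germline gene held silent by DNA methylation in most tissues (62.9 ± 45.5 to 6.97 ± 4.78 FPKM; log2 fold change -2.94, SE 0.32, limma adjusted p = 4.21e-17). The polyamine acetyltransferase relative SAT2 fell from 6.26 ± 0.0726 to 0.0498 ± 0.0704 FPKM (log2 fold change -2.79, SE 0.25, limma adjusted p = 1.35e-24), and the calcium-binding protein S100A14 from 112 ± 57.1 to 18.8 ± 4.84 FPKM (log2 fold change -2.44, SE 0.31, limma adjusted p = 4.33e-12). TENM3, an adhesion protein, was listed at 0 in both libraries labelled TET3 KO against 5.097 ± 1.49 FPKM in wild type. CBLC (-2.69), PCDH10 (-2.2), KCNN4 (-2.19), ADD3 (-2.16) and SPANXA1 (-2.13) also fell, with limma adjusted p between 1.31e-19 and 7.24e-09. Without the filter on low values the calls of IFIT1, OAS1, OAS3, SLC6A14, SMIM22, TEX19, CBLC, S100A14, KCNN4, ADD3 and SPANXA1 were lost, with limma adjusted p from 0.052 for SMIM22 to 0.235 for TEX19, and that of OAS3 also without wild-type replicate 2 (0.0833). SPANXA1 and SPANXA2 have identical values, so the value cannot be assigned to either copy.

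Some interferon signalling components rose in these libraries. The transcription factor STAT1, which carries the interferon signal to the nucleus, rose from 17.2 ± 1.18 to 50.2 ± 10.8 FPKM (log2 fold change 1.48, SE 0.31, limma adjusted p = 0.000381). Its call was lost without wild-type replicate 1 (limma adjusted p = 0.0593) or wild-type replicate 2 (0.0527). IRF9 (1.26, limma adjusted p = 0.00595), IRF7 (1.25, limma adjusted p = 0.00859) and the RNA sensor DDX58 (1.19, limma adjusted p = 0.00534) rose, and each call was lost when either wild-type library was left out. Without wild-type replicate 1 their limma adjusted p values were 0.358 for IRF9, 0.355 for IRF7 and 0.56 for DDX58, and without wild-type replicate 2 they were 0.126, 0.481 and 0.262. Leaving out TET3 KO replicate 1 ended the DDX58 call (0.131), and leaving out TET3 KO replicate 2 ended those of IRF7 (0.158) and IRF9 (0.0716). IFIT3 (1.12, limma adjusted p = 0.000218) and OASL (1.14, limma adjusted p = 0.0036) rose, calls lost without wild-type replicate 2 (0.105 and 0.727), and for IFIT3 without TET3 KO replicate 1 (0.372), for OASL without wild-type replicate 1 (0.136). Without the filter on low values, none of STAT1, IRF7, IRF9, DDX58, IFIT3 and OASL passed limma's test (adjusted p from 0.134 for STAT1 to 0.347 for DDX58). MX1 (0.38, limma adjusted p = 0.746), IFIH1 (0.80, limma adjusted p = 0.284), B2M (0.33, limma adjusted p = 0.999), TAP1 (0.37, limma adjusted p = 0.999), PSMB9 (0.21, limma adjusted p = 0.999) and HLA-A (0.59, limma adjusted p = 0.698) did not pass the test, while IFNB1, CXCL10 and CD274 were too low to be tested. Of the interferon-stimulated genes, 24 of 51 rose and 27 did not pass, and adjusted over the list alone 31 rose (median 0.85, camera adjusted p = 1.01e-61, 0.111 with an estimated correlation). Among interferons, their receptors and nucleic acid sensing genes, 2 of 17 rose and 15 did not pass (median 0.18, camera adjusted p = 0.000264, 0.2 with an estimated correlation). Chemokines and immune checkpoint ligands gave 2 rises, the T-cell attractant CCL5 (0.88, limma adjusted p = 0.0216) and the neutrophil attractant CXCL8 (1.21, limma adjusted p = 8.38e-05), with 8 of 10 not passing (median 0.19, camera adjusted p = 0.0103, 0.264 with an estimated correlation). CCL5 passed in none of the 4 fits that left out a library. Its limma adjusted p was 0.0747 without TET3 KO replicate 2, 0.165 without TET3 KO replicate 1, 0.415 without wild-type replicate 1 and 0.463 without wild-type replicate 2. CXCL8 was lost without wild-type replicate 2 (0.0696) or TET3 KO replicate 1 (0.141). Neither passed without the filter on low values (0.198 and 0.218), nor CCL5 without the mean-variance trend (0.0985) or with voom (0.0519).

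At most 3 members of each further list passed limma's test in the MCF7 libraries labelled TET3 KO. For p53 target genes, 1 of 25 fell and 24 did not pass (median -0.21, camera adjusted p = 0.00088, 0.367 with an estimated correlation), the faller being the cytokine GDF15 (-1.3, limma adjusted p = 0.00314). For the integrated stress and unfolded protein response, 2 of 30 fell and 28 did not pass, and adjusted over the list alone 5 fell (median -0.14, camera adjusted p = 0.0389, 0.476 with an estimated correlation), with the amino acid carrier SLC7A5 (-1.12, limma adjusted p = 0.0158) and DDIT4 (-1.01, limma adjusted p = 0.0446) called. Of the mesenchymal transition genes, 3 of 13 rose and 10 did not pass, and adjusted over the list alone 5 rose (median 0.17, camera adjusted p = 0.00311, 0.246 with an estimated correlation), including CTGF (1.56, limma adjusted p = 3.61e-07) and LOXL2 (1.27, limma adjusted p = 0.000136). The libraries labelled TET3 KO held 11.4 and 0.882 FPKM of CTGF. Of the ribosomal proteins, 1 of 35 fell and 34 did not pass (median -0.13, camera adjusted p = 0.00941, 0.624 with an estimated correlation), the faller being RPL10 (-1.19, limma adjusted p = 0.00715). GDF15, SLC7A5, DDIT4, CTGF and RPL10 lost their calls without TET3 KO replicate 1 (limma adjusted p = 0.724, 0.876, 0.971, 0.973 and 0.297) or without wild-type replicate 2 (1, 1, 1, 0.903 and 0.144). None of them passed without the filter on low values, nor did LOXL2 and TFF3 (limma adjusted p from 0.311 for RPL10 to 0.863 for CTGF). LOXL2 lost its call without TET3 KO replicate 2 (0.21) or wild-type replicate 2 (1), and DDIT4 also without wild-type replicate 1 (0.0501). Luminal lineage genes had 1 rise, AREG, and 1 fall, the mucosal peptide TFF3 (-1.06, limma adjusted p = 0.0443), of 27 measured (median 0.090, camera adjusted p = 0.129). The TFF3 call was kept in the fit without TET3 KO replicate 2 and lost without TET3 KO replicate 1 (0.939), wild-type replicate 1 (0.146) or wild-type replicate 2 (1) and with voom (0.0583). DNA methylation machinery had 1 rise of 21 measured, TET2 (median 0.12, camera adjusted p = 0.777). No member passed limma's test over all genes among 17 MHC class I antigen presentation genes (median 0.33, camera adjusted p = 0.00446, 0.299 with an estimated correlation), 18 NF-kB response genes (median 0.12, camera adjusted p = 0.462), 36 cell division genes (median 0.28, camera adjusted p = 0.0103, 0.659 with an estimated correlation), 24 cholesterol synthesis genes (median 0.25, camera adjusted p = 0.0103, 0.256 with an estimated correlation) or 28 hypoxia and glycolysis genes (median -0.29, camera adjusted p = 0.00105, 0.566 with an estimated correlation). At an unadjusted p under 0.05 there were 1, 1, 2, 3 and 5 members in those lists, and voom called none in the first 4 and 1 in the last. The same held for 4 germline genes (median -0.28, camera adjusted p = 0.0225, 0.419 with an estimated correlation), 3 haematopoietic cell markers (median -0.25, mean 0.020, camera adjusted p = 0.888), 1 fibroblast marker (median 0.15, no list test) and 18 replication-dependent histone genes (median 0.057, camera adjusted p = 0.711), with 1, 1, 0 and 3 members at an unadjusted p under 0.05 and no voom call. Adjusted over the list alone, 1 germline gene fell. Across 12150 genes tested, 238 passed limma's test, 114 higher and 124 lower, and 173 of them changed at least 2-fold. Without the filter on low values 48 of 16787 genes passed, 24 of them among the 238. The count was 62 without wild-type replicate 2 and 115 without TET3 KO replicate 1.

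Interferon-stimulated genes rose with either hairpin. IFI6 rose from 17.3 ± 0.473 to 422 ± 21.7 FPKM with shTET3-1 (log2 fold change 4.53, SE 0.049, limma adjusted p = 1e-10). With shTET3-2 IFI6 reached 296 ± 15.1 FPKM (log2 fold change 4.02, SE 0.049, limma adjusted p = 1.49e-10). ISG15 rose from 15.8 ± 0.437 to 142 ± 5.52 FPKM with shTET3-1 (log2 fold change 3.08, SE 0.041, limma adjusted p = 3.18e-10). With shTET3-2 ISG15 reached 180.3 ± 2.59 FPKM (log2 fold change 3.43, SE 0.041, limma adjusted p = 1.49e-10). IFITM1, which hinders virus entry at the membrane, rose from 19.8 ± 0.954 to 137 ± 6.35 FPKM with shTET3-1 (log2 fold change 2.72, SE 0.047, limma adjusted p = 2.36e-09). With shTET3-2 IFITM1 reached 90.7 ± 1.89 FPKM (log2 fold change 2.14, SE 0.047, limma adjusted p = 6.99e-09). The other leading risers were IFI27 (2.89 with shTET3-1 and 3.34 with shTET3-2), OAS1 (2.88 and 3.24), IFIT1 (2.18 and 2.18), IRF9 (1.9 and 1.87), HERC6 (1.94 and 1.68), OAS3 (1.61 and 2.23) and IRF7 (1.58 and 1.49). The protease inhibitor TIMP3, which restrains matrix breakdown, fell from 22 ± 0.755 to 3.76 ± 0.151 FPKM with shTET3-1 (log2 fold change -2.27, SE 0.051, limma adjusted p = 1.12e-08). With shTET3-2 TIMP3 reached 6.06 ± 0.132 FPKM (log2 fold change -1.7, SE 0.051, limma adjusted p = 4.57e-08). The neuroendocrine granule protein CHGA fell from 9.69 ± 1.39 to 2.81 ± 0.404 FPKM with shTET3-1 (log2 fold change -1.49, SE 0.096, limma adjusted p = 8.3e-06). With shTET3-2 CHGA reached 2.303 ± 0.124 FPKM (log2 fold change -1.69, SE 0.096, limma adjusted p = 2.67e-06). CALB2 (-1.07 and -1.2), RPRM (-1.24 and -1.06), NKAIN1 (-1.04 and -1.41) and EFHD1 (-1.46 and -0.95) fell with shTET3-1 and shTET3-2. SPANXA1 and SPANXA2 fell by the same amount (-1.08 and -1.39). HOTS, read from the strand opposite H19, was lower as well (-1.78 and -1.1), but the strand setting of the libraries was not given and the value is uncertain.

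STAT1, RNA sensors and B2M rose with both hairpins. STAT1 went from 10.98 ± 0.543 to 25.3 ± 0.0542 FPKM with shTET3-1 (log2 fold change 1.14, SE 0.047, limma adjusted p = 4.79e-07). With shTET3-2 STAT1 reached 30.9 ± 1.06 FPKM (log2 fold change 1.41, SE 0.047, limma adjusted p = 1.11e-07). IFIH1 (1.4 and 1.4), DDX58 (0.96 and 1.03), IFIT3 (0.90 and 1.12), OASL (1.05 and 1.57) and CCL5 (0.94 and 1.11) rose with both. B2M, the invariant chain of MHC class I, rose from 62.1 ± 0.612 to 87.7 ± 0.0354 FPKM with shTET3-1 (log2 fold change 0.49, SE 0.034, limma adjusted p = 1.18e-05). With shTET3-2 B2M reached 105 ± 0.368 FPKM (log2 fold change 0.75, SE 0.034, limma adjusted p = 6.28e-07). The peptide transporter TAP1 rose by 0.70 and 1.18, and the immunoproteasome subunit PSMB9 by 0.95 and 2.02 on the log2 scale. HLA-A, whose reads are shared with related genes, passed with shTET3-2 (0.60, limma adjusted p = 0.000196) and not with shTET3-1 (0.18, limma adjusted p = 0.0759, 0.0499 without shTET3-1 replicate 1). Of the interferon-stimulated genes with shTET3-1, 46 of 49 rose, 1 fell and 2 did not pass (median 0.94, camera adjusted p = 1.25e-30, 0.0372 with an estimated correlation, 0.121 with a replicate block as well). The faller was TRIM14 (-0.22, limma adjusted p = 0.0178), a call lost without the filter on low values (0.0582), without shscramble replicate 2 (0.101) and without shTET3-1 replicate 1 (0.0793). MX1 rose by 0.26 with shTET3-1, a call lost without shscramble replicate 2 (limma adjusted p = 0.104) or shTET3-1 replicate 1 (0.109). With shTET3-2, 49 of 49 interferon-stimulated genes rose (median 1.12, camera adjusted p = 3.74e-29, 0.0372 with an estimated correlation, 0.121 with a replicate block as well). Among MHC class I antigen presentation genes, 11 of 17 rose and 6 did not pass, and adjusted over the list alone 14 rose (median 0.25, camera adjusted p = 4.57e-06, 0.111 with an estimated correlation) with shTET3-1, while 17 of 17 rose with shTET3-2 (median 0.61, camera adjusted p = 5.96e-10, 0.111 with an estimated correlation). For interferons, their receptors and nucleic acid sensing, 7 of 16 rose and 1 fell (median 0.13, camera adjusted p = 0.0845, 2 fell with a replicate block) with shTET3-1 and 10 of 16 rose and 6 did not pass (median 0.29, camera adjusted p = 0.00311, 0.191 with an estimated correlation) with shTET3-2. SOCS3, which dampens cytokine signalling, fell with shTET3-1 (-0.33, limma adjusted p = 0.00363), and the kinase IKBKE rose with shTET3-2 (1.51, limma adjusted p = 3.61e-07).

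RELB, MSMO1 and TFF1 rose with shTET3-2. The NF-kB subunits RELB (1.21, limma adjusted p = 3.53e-06) and NFKB2 (0.76, limma adjusted p = 4.99e-06) rose with shTET3-2. The oestrogen receptor ESR1 rose with shTET3-1 (0.36, limma adjusted p = 0.000141), and the oestrogen target TFF1 rose from 2854 ± 40.1 to 4760.2 ± 133 FPKM with shTET3-2 (log2 fold change 0.74, SE 0.038, limma adjusted p = 1.3e-06). Of the NF-kB response genes with shTET3-1, 2 of 15 rose and 3 fell (median -0.038, camera adjusted p = 0.285, 5 fell with a replicate block). With shTET3-2, 10 of 15 rose and 5 did not pass, and adjusted over the list alone 10 rose and 1 fell (median 0.26, camera adjusted p = 0.00358, 0.264 with an estimated correlation, 2 fell with a replicate block). Of the replication-dependent histone genes with shTET3-1, 10 of 14 rose and 4 did not pass, and adjusted over the list alone 11 rose (median 0.53, camera adjusted p = 2.23e-05, 0.198 with an estimated correlation), HIST2H2BE among them (0.86, limma adjusted p = 6.62e-06). With shTET3-2, 4 of 14 rose and 3 fell (median 0.15, camera adjusted p = 0.4). These libraries were made from polyadenylated RNA, whereas most mRNAs of these histone genes lack a poly(A) tail. Of the cholesterol synthesis genes with shTET3-1, 12 of 24 rose and 12 did not pass, and adjusted over the list alone 14 rose (median 0.14, camera adjusted p = 0.00162, 0.167 with an estimated correlation). With shTET3-2, 12 of 24 rose and 12 did not pass (median 0.12, camera adjusted p = 0.0389, 0.251 with an estimated correlation, 2 fell with a replicate block). The sterol oxidase MSMO1 rose by 0.56 and 0.56 on the log2 scale. Of the hypoxia and glycolysis genes with shTET3-1, 2 of 26 rose, 11 fell and 13 did not pass, and adjusted over the list alone 2 rose and 13 fell (median -0.10, camera adjusted p = 0.000625, 0.156 with an estimated correlation), PFKFB4 (-0.55) and ALDOC (-0.49) among the fallers. With shTET3-2, 10 of 26 rose and 3 fell (median 0.090, camera adjusted p = 0.271). Of the p53 target genes with shTET3-1, 7 of 24 rose and 3 fell (median 0.073, camera adjusted p = 0.368). With shTET3-2, 16 of 24 rose, 2 fell and 6 did not pass, and adjusted over the list alone 17 rose and 2 fell (median 0.28, camera adjusted p = 0.00296, 0.18 with an estimated correlation), and TP53INP1 rose with both (0.46 and 0.56). Of the mesenchymal transition genes with shTET3-1, 3 of 13 rose, 7 fell and 3 did not pass, and adjusted over the list alone 4 rose and 7 fell (median -0.30, camera adjusted p = 0.0466, 0.376 with an estimated correlation, 0.0677 with a replicate block). With shTET3-2, 7 of 13 rose and 1 fell (median 0.24, camera adjusted p = 0.213), and the matrix protein TGFBI went in opposite directions (-0.50 and 1.05).

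Ribosomal protein genes moved down with shTET3-2, where RPSA fell from 2335 ± 56.7 to 1330.4 ± 10.8 FPKM (log2 fold change -0.81, SE 0.036, limma adjusted p = 5.93e-07) and 19 of 35 fell and 16 did not pass, and adjusted over the list alone 22 fell (median -0.17, camera adjusted p = 5.96e-10, 0.278 with an estimated correlation). With shTET3-1, 3 of 35 fell and 32 did not pass, and adjusted over the list alone 2 fell (median -0.056, camera adjusted p = 0.00891, 0.528 with an estimated correlation, 12 fell with a replicate block). Of the luminal lineage genes with shTET3-1, 11 of 27 rose and 6 fell (median 0.067, camera adjusted p = 0.28). With shTET3-2, 7 of 27 rose and 8 fell (median 0.014, -0.030 after rescaling, camera adjusted p = 0.486, test direction down). Of the stress and unfolded protein response genes with shTET3-1, 13 of 30 rose and 3 fell (median 0.11, camera adjusted p = 0.129), XBP1 among the risers (0.54). With shTET3-2, 16 of 30 rose and 4 fell (median 0.17, camera adjusted p = 0.067). Of the cell division genes with shTET3-1, 8 of 36 rose and 10 fell (median -0.0083, camera adjusted p = 0.462). With shTET3-2, 14 of 36 rose and 9 fell (median 0.035, -0.0068 after rescaling, camera adjusted p = 0.888, test direction down), and the mitotic kinase AURKA rose with both (0.25 and 0.42). Of the DNA methylation machinery with shTET3-1, 5 of 19 rose and 3 fell (median 0.043, camera adjusted p = 0.535). With shTET3-2, 8 of 19 rose and 2 fell (median 0.14, camera adjusted p = 0.172), and UHRF1, which directs maintenance methylation, fell with both (-0.18 and -0.20). Of the chemokines and immune checkpoint ligands with shTET3-1, 2 of 7 rose and 1 fell (median 0.095, camera adjusted p = 0.271). With shTET3-2, 3 of 7 rose and 1 fell (median 0.018, -0.025 after rescaling, camera adjusted p = 0.368). None of 3 germline genes passed limma's test with shTET3-1 (median -0.015, camera adjusted p = 0.462), against 1 faller at an unadjusted p under 0.05, 1 by voom and 1 with a replicate block, and 1 of 3 fell with shTET3-2 (median -0.093, camera adjusted p = 0.186). Of 3 haematopoietic cell markers, CD68 fell with shTET3-1 (median -0.17, camera adjusted p = 0.36), and 0 passed limma, voom or an unadjusted p under 0.05 with shTET3-2 (median 0.095, camera adjusted p = 0.745). The 1 fibroblast marker measured did not pass limma's test with shTET3-1 (median 0.11, no list test) or shTET3-2 (median 0.16, no list test), although it passed voom and an unadjusted p under 0.05 with shTET3-2. Of 11739 genes tested, 3846 passed limma's test with shTET3-1, 2235 higher and 1611 lower, and 77 changed at least 2-fold. With shTET3-2, 5138 passed, 3364 higher and 1774 lower, and 112 changed at least 2-fold. Rescaling all libraries to equal median ratios gave 1755 higher and 1955 lower with shTET3-1 and 2707 higher and 2304 lower with shTET3-2.

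**Figure D2:**
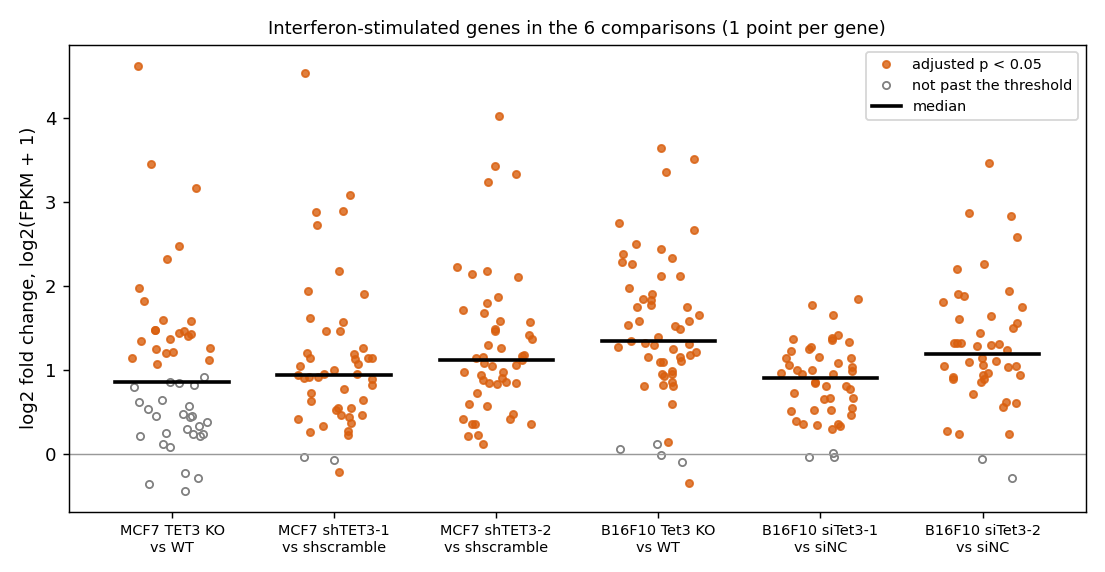
Log2 fold changes (log2(FPKM + 1) scale) of interferon-stimulated genes in the 6 comparisons, with a point for each gene. ISG15, IFIT1, STAT1 and IRF9 lie above 0 in every comparison.

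Cxcl1, Ccl2, Cp and Fn1 were among the largest rises in the B16F10 libraries labelled Tet3 KO. Cxcl1, which attracts neutrophils, rose from 0.0177 ± 0.0251 to 70.9 ± 2.503 FPKM (log2 fold change 6.14, SE 0.055, limma adjusted p = 1.67e-11), and the monocyte attractant Ccl2 was listed at 0 in both wild-type libraries against 27.7 ± 1.603 FPKM. Cxcl10, an interferon-induced attractant of T cells, rose from 3.75 ± 0.144 to 79.8 ± 1.95 FPKM (log2 fold change 4.09, SE 0.042, limma adjusted p = 2.37e-11). The copper carrier Cp rose from 6.85 ± 0.0465 to 187 ± 4.05 FPKM (log2 fold change 4.58, SE 0.033, limma adjusted p = 4.98e-12) and fibronectin, Fn1, from 13.6 ± 0.326 to 224 ± 0.288 FPKM (log2 fold change 3.95, SE 0.030, limma adjusted p = 4.98e-12). Slpi (4.65), Rgs16 (4.23), Cebpd (4.05), Ccn1 (3.91) and Igfbp7 (3.9) completed the largest rises. The gap junction protein Gjb2 fell from 97.2 ± 0.234 to 5.13 ± 0.309 FPKM (log2 fold change -4.0, SE 0.043, limma adjusted p = 2.74e-11), the growth factor receptor Met from 162 ± 0.0531 to 19.6 ± 0.366 FPKM (log2 fold change -2.99, SE 0.029, limma adjusted p = 1.86e-11) and the electron carrier Cyb5a from 528 ± 2.74 to 80.9 ± 2.36 FPKM (log2 fold change -2.69, SE 0.026, limma adjusted p = 1.86e-11). Cbr3 (-3.75), Aldoc (-3.62), Cited1 (-3.27), Gsta4 (-2.76), Tor4a (-2.74) and St6gal1 (-2.65) fell as well, and Btn2a2 was listed at 0 in both libraries labelled Tet3 KO against 5.68 ± 0.163 FPKM in wild type.

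Interferon-stimulated genes rose in these libraries. Isg15 rose from 3.999 ± 0.938 to 49.6 ± 0.8401 FPKM (log2 fold change 3.35, SE 0.10, limma adjusted p = 9.92e-09), Oas1a from 1.41 ± 0.144 to 29.1 ± 1.07 FPKM (log2 fold change 3.64, SE 0.061, limma adjusted p = 4.27e-10) and Stat1 from 9.49 ± 0.0459 to 32.04 ± 1.004 FPKM (log2 fold change 1.65, SE 0.041, limma adjusted p = 3.29e-09). Irf9 (1.83), the RNA sensors Ddx58 (2.6) and Ifih1 (1.5), Ifit1 (1.4), Ifit3 (0.93) and Ccl5 (1.24) rose too, while Mx1 (0.055, limma adjusted p = 0.586) and the checkpoint ligand Cd274 (-0.15, limma adjusted p = 0.176) did not pass. Irf7, Ifnb1, Oasl1 and Psmb9 were under the expression filter. Of the interferon-stimulated genes, 50 of 55 rose, 1 fell and 4 did not pass, and adjusted over the list alone 50 rose and 2 fell (median 1.34, camera adjusted p = 3.91e-12, 0.111 with an estimated correlation), the faller being Ifitm2 (-0.35, limma adjusted p = 2.82e-06). For interferons, their receptors and nucleic acid sensing, 14 of 21 rose and 4 fell (median 0.49, camera adjusted p = 0.106), with Mavs (-0.30) and Ifnar2 (-0.41) among the fallers. B2m rose from 107 ± 0.155 to 257 ± 2.26 FPKM (log2 fold change 1.25, SE 0.022, limma adjusted p = 5.74e-10), and H2-K1, whose reads are shared with related genes, from 5.15 ± 0.443 to 28.3 ± 1.096 FPKM (log2 fold change 2.25, SE 0.059, limma adjusted p = 4.03e-09). For MHC class I antigen presentation, 17 of 18 rose and 1 did not pass (median 0.87, camera adjusted p = 2.42e-06, 0.167 with an estimated correlation). Of the chemokines and immune checkpoint ligands, 9 of 11 rose and 2 did not pass (median 0.94, camera adjusted p = 0.00144, 0.226 with an estimated correlation). All 15 NF-kB response genes measured rose (median 1.11, camera adjusted p = 3.79e-05, 0.191 with an estimated correlation), with Csf1 (2.78) and Nfkbia (2.1) leading.

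Pigment lineage genes fell in the B16F10 libraries labelled Tet3 KO, where 1 of 22 rose and 21 fell (median -1.01, camera adjusted p = 4.57e-13, 0.111 with an estimated correlation). The melanosome antigen Mlana fell from 1702 ± 6.16 to 703 ± 7.79 FPKM (log2 fold change -1.27, SE 0.018, limma adjusted p = 2.04e-10). The riser, Sox5 (0.19, limma adjusted p = 0.0347), lost its call after rescaling (0.068) and without the filter on low values (0.054), wild-type replicate 1 (0.172), Tet3 KO replicate 1 (0.0553) or Tet3 KO replicate 2 (0.14). Cell division genes followed, where 5 of 36 rose, 28 fell and 3 did not pass, and adjusted over the list alone 6 rose and 28 fell (median -0.45, camera adjusted p = 5.14e-09, 0.278 with an estimated correlation), with cyclin Ccnb1 going from 152 ± 1.702 to 56.7 ± 1.66 FPKM (log2 fold change -1.41, SE 0.029, limma adjusted p = 1.17e-09) and Cenpe rising (0.90). Of p53 target genes, 16 of 21 rose, 3 fell and 2 did not pass (median 0.58, camera adjusted p = 0.00772, 0.251 with an estimated correlation), with Cdkn1a (1.35) and Btg2 (2.08) up. Of the mesenchymal transition genes, 17 of 20 rose, 2 fell and 1 did not pass (median 0.95, camera adjusted p = 8.91e-05, 0.264 with an estimated correlation). All 4 fibroblast markers measured rose (median 1.03, camera adjusted p = 0.0684), among them collagen Col1a1 (2.23). Of the hypoxia and glycolysis genes, 21 of 28 rose, 6 fell and 1 did not pass (median 0.48, camera adjusted p = 0.0136, 0.424 with an estimated correlation), with Bnip3 up (2.02) and Ndrg1 down (-1.29). Of the cholesterol synthesis genes, 3 of 23 rose, 15 fell and 5 did not pass (median -0.17, camera adjusted p = 0.00242, 0.342 with an estimated correlation), with Msmo1 down (-0.59). Of the ribosomal protein genes, 9 of 35 rose, 19 fell and 7 did not pass, and adjusted over the list alone 9 rose and 20 fell (median -0.074, camera adjusted p = 0.000933, 0.451 with an estimated correlation), or 4 rising and 24 falling after rescaling, with Rps18 down (-0.42). Of the stress and unfolded protein response genes, 17 of 28 rose and 7 fell (median 0.22, camera adjusted p = 0.234), Atf3 rising most clearly (3.22). Of the DNA methylation machinery, 8 of 19 rose and 5 fell (median 0.12, camera adjusted p = 0.918, test direction down), with Dnmt3a up (0.93) and Uhrf1 down (-0.48). Of 3 haematopoietic cell markers, Lyz2 rose (0.94) and Cd68 (-1.21) and Fcer1g (-1.13) fell (median -1.13, camera adjusted p = 0.271). The 1 germline gene measured did not pass limma's test over all genes (median 0.23, no list test), passed adjusted over the list alone and at an unadjusted p under 0.05, and was not called by voom. Of 10946 genes tested, 8295 passed limma's test, 5185 higher and 3110 lower, and 669 changed at least 2-fold, 497 of them higher. The median of all genes was shifted by 0.11, and after rescaling 4720 were higher and 3501 lower.

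Agt, Ccl5 and Ddx58 rose with both B16F10 siRNAs. Angiotensinogen, Agt, rose from 1.18 ± 0.01102 to 18.5 ± 0.931 FPKM with siTet3-1 (log2 fold change 3.16, SE 0.050, limma adjusted p = 1.25e-09). With siTet3-2 Agt reached 15.3 ± 0.169 FPKM (log2 fold change 2.9, SE 0.050, limma adjusted p = 1.08e-09). The T-cell attractant Ccl5 rose from 2.03 ± 0.681 to 10.8 ± 0.4405 FPKM with siTet3-1 (log2 fold change 1.98, SE 0.12, limma adjusted p = 8.09e-07). With siTet3-2 Ccl5 reached 24.1 ± 0.968 FPKM (log2 fold change 3.07, SE 0.12, limma adjusted p = 3.99e-08). Isg15 rose from 0.917 ± 0.0983 to 5.55 ± 0.232 FPKM with siTet3-1 (log2 fold change 1.77, SE 0.061, limma adjusted p = 3.96e-08). With siTet3-2 Isg15 reached 10.4 ± 0.328 FPKM (log2 fold change 2.58, SE 0.061, limma adjusted p = 2.82e-09). The RNA sensors Ddx58 (1.85 with siTet3-1 and 2.07 with siTet3-2) and Dhx58 (1.55 and 1.42) rose, as did Rtp4 (1.84 and 2.83), Ankrd52 (1.81 and 1.99), Ip6k3 (1.87 and 1.68), C1qtnf5 (1.51 and 1.58) and Asb2 (1.5 and 1.84). Psat1, an enzyme of serine synthesis, fell from 99.5 ± 0.201 to 33.98 ± 0.386 FPKM with siTet3-1 (log2 fold change -1.52, SE 0.029, limma adjusted p = 3.18e-09). With siTet3-2 Psat1 reached 39.02 ± 0.7199 FPKM (log2 fold change -1.33, SE 0.029, limma adjusted p = 1.76e-09). The DNA polymerase delta subunits Pold1 (-1.11 and -1.04) and Pold2 (-1.05 and -1.02), the chaperone Hspa1b (-1.39 and -1.84), Rasd2 (-1.43 and -1.33), the proline enzyme Pycr1 (-1.16 and -1.33), Nsl1 (-1.09 and -1.1) and Ube2t (-0.98 and -1.31) fell with both. The histone gene H3c4 fell from 104 ± 66.8 FPKM, a control value with wide spread (-1.53 and -1.33), and its call with siTet3-2 was lost without the filter on low values (limma adjusted p = 0.051).

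Interferon targets rose with both siRNAs. Ifit3 rose from 1.37 ± 0.0454 to 3.84 ± 0.0724 FPKM with siTet3-1 (log2 fold change 1.03, SE 0.051, limma adjusted p = 2.51e-07). With siTet3-2 Ifit3 reached 25.3 ± 0.709 FPKM (log2 fold change 3.47, SE 0.051, limma adjusted p = 4.69e-10). Stat1 rose from 7.05 ± 0.1895 to 15.8 ± 1.22 FPKM with siTet3-1 (log2 fold change 1.06, SE 0.052, limma adjusted p = 2.28e-07). With siTet3-2 Stat1 reached 27.2 ± 0.123 FPKM (log2 fold change 1.81, SE 0.052, limma adjusted p = 6.69e-09). Irf9 rose from 1.39 ± 0.0741 to 5.38 ± 0.0807 FPKM with siTet3-1 (log2 fold change 1.42, SE 0.054, limma adjusted p = 6.2e-08). With siTet3-2 Irf9 reached 9.98 ± 0.191 FPKM (log2 fold change 2.2, SE 0.054, limma adjusted p = 3.3e-09). Irf7 (1.37 and 1.94), Ifit1 (0.39 and 1.64), Mx1 (0.52 and 1.24), Oas1a (1.16 and 0.94), Ifih1 (0.55 and 1.14) and Cxcl10 (0.94 and 0.92) rose with both. Ifnb1 was listed at 0 in every library of the table, Oasl1 and Psmb9 were under the expression filter, and Cd274 did not pass with siTet3-1 (0.025, limma adjusted p = 0.781) or siTet3-2 (0.057, limma adjusted p = 0.503). Of the interferon-stimulated genes with siTet3-1, 43 of 46 rose and 3 did not pass (median 0.90, camera adjusted p = 2.87e-13, 0.111 with an estimated correlation). With siTet3-2, 44 of 46 rose and 2 did not pass (median 1.19, camera adjusted p = 1.22e-11, 0.111 with an estimated correlation), and 2 fell after rescaling. Of the interferons, their receptors and nucleic acid sensing genes with siTet3-1, 15 of 19 rose, 3 fell and 1 did not pass (median 0.34, camera adjusted p = 0.00591, 0.308 with an estimated correlation). With siTet3-2, 17 of 19 rose, 1 fell and 1 did not pass (median 0.52, camera adjusted p = 0.0018, 0.278 with an estimated correlation), and Mavs, the adaptor of the RNA sensors, fell with both (-0.32 and -0.63). Of the MHC class I antigen presentation genes with siTet3-1, 14 of 18 rose and 4 did not pass, and adjusted over the list alone 15 rose (median 0.40, camera adjusted p = 4.58e-05, 0.126 with an estimated correlation). With siTet3-2, 13 of 18 rose and 5 did not pass (median 0.35, camera adjusted p = 0.0171, 0.226 with an estimated correlation), and 2 fell after rescaling. B2m rose with siTet3-1 (0.44, limma adjusted p = 4.46e-06) and siTet3-2 (0.54, limma adjusted p = 9.02e-07), and so did Tap1 (0.41 and 0.25), although its siTet3-2 call was lost without siNC replicate 1 (limma adjusted p = 0.0752). H2-K1 rose with siTet3-1 (0.58, limma adjusted p = 3.37e-06) and did not pass with siTet3-2 (-0.032, limma adjusted p = 0.53), where it became a fall after rescaling (-0.14, limma adjusted p = 0.022) or without siNC replicate 1 (-0.11, 0.0339). Of the chemokines and immune checkpoint ligands with siTet3-1, 5 of 9 rose and 4 did not pass (median 0.40, camera adjusted p = 0.0115, 0.226 with an estimated correlation). With siTet3-2, 4 of 9 rose and 3 fell (median 0.15, camera adjusted p = 0.845, test direction down). Of the NF-kB response genes with siTet3-1, 13 of 15 rose and 2 did not pass (median 0.60, camera adjusted p = 0.000113, 0.246 with an estimated correlation), Bcl3 among them (1.95). With siTet3-2, 4 of 15 rose and 4 fell (median 0.0096, mean -0.036, -0.084 after rescaling, camera adjusted p = 0.304, test direction down), Nfkbia falling (-0.61).

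Cell division genes fell with the siRNAs, the origin licensing factor Cdt1 going from 38.4 ± 0.462 to 12.9 ± 0.307 FPKM with siTet3-1 (log2 fold change -1.5, SE 0.035, limma adjusted p = 7.91e-09). With siTet3-2 Cdt1 reached 19.5 ± 0.285 FPKM (log2 fold change -0.94, SE 0.035, limma adjusted p = 3.26e-08). Of the cell division genes with siTet3-1, 34 of 35 fell and 1 did not pass (median -0.58, camera adjusted p = 2.11e-14, 0.111 with an estimated correlation). With siTet3-2, 33 of 35 fell and 2 did not pass (median -0.64, camera adjusted p = 3.7e-17, 0.111 with an estimated correlation). Pigment lineage genes rose with siTet3-2, where Mlana went from 566 ± 15.7 to 1643 ± 17.1 FPKM (log2 fold change 1.54, SE 0.025, limma adjusted p = 1.02e-09) and 18 of 23 rose, 2 fell and 3 did not pass (median 0.75, camera adjusted p = 0.000228, 0.305 with an estimated correlation). With siTet3-1, 8 of 23 rose and 11 fell (median -0.052, camera adjusted p = 0.282). The pigment enzyme Tyrp1 fell with both (-0.93 and -0.31). Of the cholesterol synthesis genes with siTet3-1, 5 of 23 rose and 12 fell (median -0.16, camera adjusted p = 0.0924). With siTet3-2, 2 of 23 rose, 18 fell and 3 did not pass, and adjusted over the list alone 2 rose and 19 fell (median -0.40, camera adjusted p = 2.29e-08, 0.167 with an estimated correlation), the receptor Ldlr among the fallers (-1.4). Of the hypoxia and glycolysis genes with siTet3-1, 7 of 28 rose and 15 fell (median -0.087, camera adjusted p = 0.181). With siTet3-2, 4 of 28 rose, 18 fell and 6 did not pass, and adjusted over the list alone 5 rose and 18 fell (median -0.19, camera adjusted p = 4.25e-05, 0.14 with an estimated correlation), Eno2 among the fallers (-1.98). Of the ribosomal protein genes with siTet3-1, 31 of 35 fell and 4 did not pass (median -0.38, camera adjusted p = 9.98e-10, 0.111 with an estimated correlation). With siTet3-2, 5 of 35 rose, 18 fell and 12 did not pass, and adjusted over the list alone 4 rose and 17 fell (median -0.098, camera adjusted p = 0.000625, 0.2 with an estimated correlation), or 0 rising and 21 falling after rescaling. Of the mesenchymal transition genes with siTet3-1, 12 of 17 rose, 2 fell and 3 did not pass, and adjusted over the list alone 12 rose and 3 fell (median 0.20, camera adjusted p = 0.0103, 0.308 with an estimated correlation). With siTet3-2, 6 of 17 rose and 8 fell (median -0.084, camera adjusted p = 0.155), and Fn1 fell with both (-0.57 and -1.14). Of the stress and unfolded protein response genes with siTet3-1, 14 of 29 rose and 10 fell (median 0.098, mean -0.019, camera adjusted p = 0.845), Hspa5 rising (0.76). With siTet3-2, 8 of 29 rose, 14 fell and 7 did not pass (median -0.14, camera adjusted p = 0.00311, 0.218 with an estimated correlation). Of the p53 target genes with siTet3-1, 8 of 21 rose and 8 fell (median 0.080, camera adjusted p = 0.835). With siTet3-2, 9 of 21 rose and 9 fell (median 0.042, mean -0.00096, -0.030 after rescaling, camera adjusted p = 0.356, test direction down), and the cell cycle inhibitor Cdkn1a went up with siTet3-1 (0.36) and down with siTet3-2 (-0.99). Of the DNA methylation machinery with siTet3-1, 5 of 19 rose and 8 fell (median -0.082, camera adjusted p = 0.341). With siTet3-2, 10 of 19 rose and 7 fell (median 0.17, camera adjusted p = 0.745, test direction down), and Uhrf1 fell with both (-1.04 and -0.71). Both fibroblast markers measured rose with siTet3-1 (median 0.86, no list test) and 1 of 2 with siTet3-2 (median 0.53, no list test). The 1 haematopoietic cell marker measured, Cd68, rose with siTet3-1 (0.22, limma adjusted p = 0.0227) and fell with siTet3-2 (-0.95, limma adjusted p = 2.19e-06). Its rise lost its call without the filter on low values (0.0591), with voom (0.0775) and without siNC replicate 1 (0.0668), siNC replicate 2 (0.0883) or siTet3-1 replicate 1 (0.149). Of 10607 genes tested, 6898 passed limma's test with siTet3-1, 3593 higher and 3305 lower, and 236 changed at least 2-fold. With siTet3-2, 7449 passed, 4888 higher and 2561 lower, and 378 changed at least 2-fold. The median of all genes was shifted by 0.108 with siTet3-2, and after rescaling 3930 were higher and 3385 lower.

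Some of these responses differed between reagents aimed at the same gene, by limma's test of their difference in the same fit. With a replicate block the list of interferons, receptors and sensing differed between hairpins (0.178, camera adjusted p = 0.0408, 0.0501 without the block, 0.26 with an estimated correlation). Interferon-stimulated genes stood higher with shTET3-2 than with shTET3-1 (median log2 difference 0.19, camera adjusted p = 0.006) and higher with siTet3-2 than with siTet3-1 (0.52, camera adjusted p = 0.0239). MHC class I antigen presentation stood higher with shTET3-2 (0.33, camera adjusted p = 4.26e-06). The pigment lineage genes stood higher with siTet3-2 (0.65, camera adjusted p = 3.5e-07) and NF-kB response genes lower (-0.72, camera adjusted p = 1.91e-05). With an estimated correlation no list difference passed, the lowest camera adjusted p being 0.195. Of 11739 genes, 5103 differed between hairpins, 2984 higher and 2119 lower with shTET3-2, and 108 at least 2-fold. Of 10607 genes, 7562 differed between siRNAs, 5033 higher and 2529 lower with siTet3-2, and 373 at least 2-fold, or 3653 higher and 3434 lower after rescaling.

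Genes called with both reagents of a cell line were counted next. Both hairpins raised 1241 genes and lowered 502 (836 and 317 without shscramble replicate 2), and 499 went in opposite directions, with 27 rising and 9 falling at least 2-fold with each. After rescaling 906 rose and 730 fell. Independent lists of the same lengths would have shared 640.5 higher and 243.5 lower genes. Both siRNAs raised 2385 and lowered 1486, and 1238 went in opposite directions, with 52 rising and 9 falling at least 2-fold with each. Independent lists would have shared 1656 higher and 798 lower. The reagents of a cell line share their control libraries, which can raise such overlaps. In 100 simulations of unchanged groups against shared controls, the mean overlap was 0.08 genes (highest 1) in MCF7 and 0.15 (2) in B16F10. With no gene changed, these cannot show how far shared controls raise overlaps. Across genes, which are not independent replicates, log2 fold changes correlated by 0.428 between hairpins (0.499 simulated) and 0.455 between siRNAs (0.5). Their covariance was 0.028 (0.00182) and 0.0778 (0.00197). The 2 control libraries could not be split, so part of the excess over independent lists may come from them.

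Libraries labelled KO and the knockdown libraries of the same line shared no controls. In MCF7, 47 of 11537 genes tested in both tables were called in the same direction in the libraries labelled TET3 KO and with both hairpins, 34 higher and 13 lower, and 24 in opposite directions. Of the 34, 23 were interferon-stimulated genes. Independent lists would have shared 10.3 higher and 4.49 lower. Fisher's exact test, two-sided, gave an odds ratio of 4.62 for higher genes (p = 1.18e-10, adjusted p = 2.36e-10 over 4 tests) and 3.21 for lower genes (p = 0.000529, adjusted p = 0.000529). The 47 became 7 without the filter on low values, 18 without wild-type replicate 2, 24 without wild-type replicate 1 and 28 without TET3 KO replicate 1. In B16F10, 1931 of 10333 genes were shared, 1217 higher and 714 lower, and 1033 went in opposite directions. After rescaling 1067 were higher and 951 lower. Independent lists would have shared 1090 higher and 423 lower. Fisher's exact test, two-sided, gave an odds ratio of 1.33 for higher genes (p = 1.43e-09, adjusted p = 1.91e-09). For lower genes Fisher's exact test, two-sided, gave 2.81 (p = 9.55e-69, adjusted p = 3.82e-68). Among the shared higher genes were 38 interferon-stimulated genes. Genes within a cell line move together, so these p-values measure overlap of lists and not of independent units. The correlation of log2 fold changes across genes was 0.126 in MCF7 and 0.0234 without the interferon-stimulated genes, and 0.138 and 0.105 in B16F10. Opposite counts were not set against independence, and overlaps were not tested without those genes.

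Interferon-stimulated genes made up most of the symbols higher in all 6 comparisons. Of 8664 symbols tested in all, 14 were higher in all 6. Independence of the 6 would give 0.115, and independence of the 4 tables, with the genes raised by both reagents as observed, 0.329. Neither is a value for unchanged groups, and the simulations above give none for this count. The 14 became 3 without the filter on low values, 2 of them among the 14. They became 5 without MCF7 wild-type replicate 2, 7 without MCF7 wild-type replicate 1 and 9 without TET3 KO replicate 1, and 30 symbols passed at an unadjusted p under 0.05 and 13 by voom. Of the 14, 10 were on the interferon-stimulated list (ISG15, IFI27, IRF9, IFIT1, IFIT3, STAT1, PARP9, IFITM3, DTX3L and IFIT2) and 4 were not (DDX58, CCL5, PARP10 and the serine protease PRSS23). PRSS23 rose by 1.72, 0.80, 1.69, 2.31, 0.84 and 0.43, in the order of the comparisons of libraries labelled TET3 KO, shTET3-1, shTET3-2, libraries labelled Tet3 KO, siTet3-1 and siTet3-2. By limma 0 symbols were lower in all 6, against 0.0252 under independence, and 0 at an unadjusted p under 0.05 or by voom. Of the 95 list tests with the preset correlation, only the calls of interferon-stimulated genes with shTET3-1 and shTET3-2 held with an estimated correlation and no block.

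**Figure D3:**
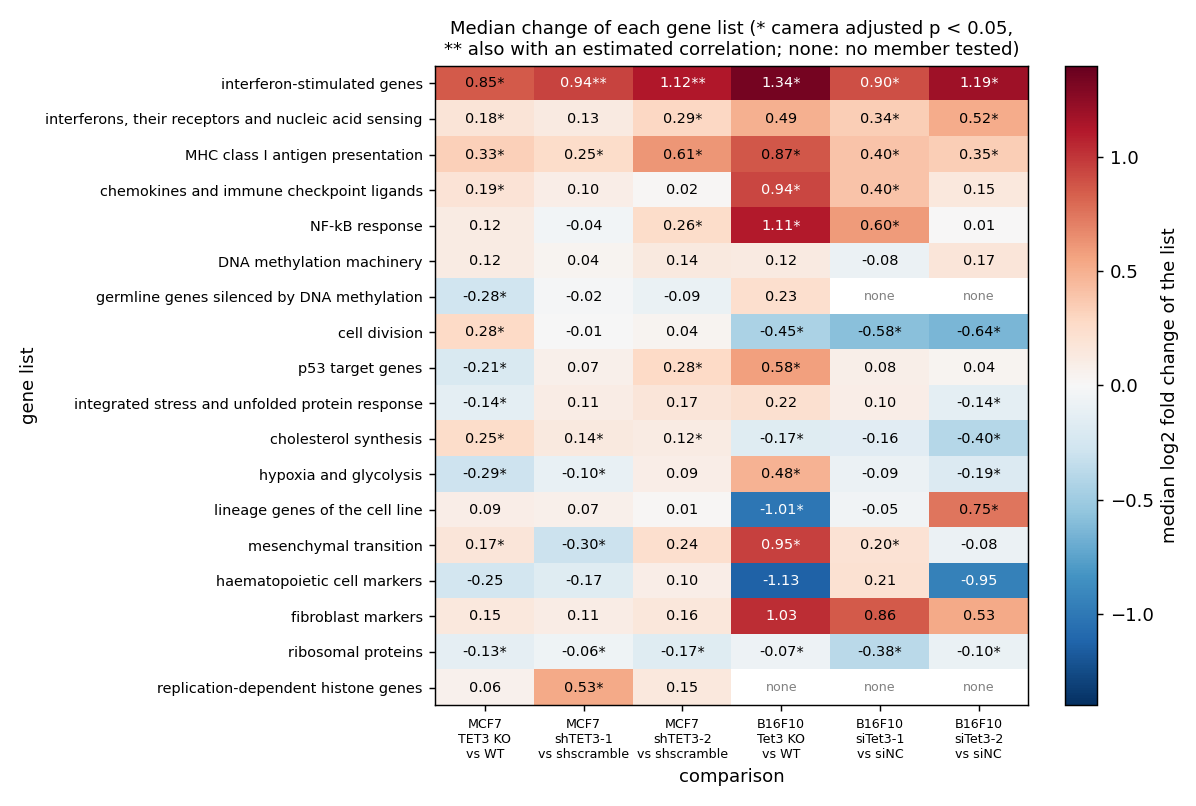
Median log2 fold change (log2(FPKM + 1) scale) of each gene list in the 6 comparisons, from the values as deposited. The interferon-stimulated genes lie between 0.85 and 1.34 in every comparison, cell division lies at -0.45 or lower in the 3 B16F10 comparisons, and the pigment lineage list goes from -1.01 in the libraries labelled Tet3 KO to 0.75 with siTet3-2.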

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

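All tests of explanations in this part were chosen after the results were seen, while the tests of differences between reagents were planned.

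Interferon-stimulated genes rose in all 6 comparisons by camera at the preset correlation, though 27 of 51 did not pass in the libraries labelled TET3 KO. With an estimated correlation 4 calls were lost (camera adjusted p = 0.111), and the other 2, with hairpins, with a replicate block as well (0.121). The tables argue against scaling and clone differences as single causes of the list's 6 medians. Scaling would take them to about 0, but after rescaling the smallest was 0.801. Differences between clones labelled KO would be missing from the hairpin and siRNA libraries, whose smallest median was 0.903. A shared response to delivered RNA stays open: how the libraries labelled KO (smaller median 0.854) were made was not given. Controls shscramble and siNC carry such RNA too. Also open are separate causes by arm, such as a reagent response in the knockdown libraries and a clone difference in those labelled KO. So is an effect of TET3 itself, although its mRNA was not lower in the libraries labelled KO.

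Tet3 mRNA was higher in the B16F10 libraries labelled Tet3 KO. Scaling is argued against, since Tet3 stayed higher by 0.95 after rescaling (limma adjusted p = 9.29e-07). Exchanged labels, with Tet3 loss acting on interferon-stimulated genes as it did with the siRNAs, would need those genes lower in the libraries labelled KO, but their median was 1.34. An edit that stops the protein and leaves the transcript cannot be told apart from an unedited gene here: the FPKM ratio of 2.15 covers the whole gene, and the tables hold no exon-level value. This difference from the siRNAs was not tested, as the tables share no libraries: Tet3 changed by 0.992 in the libraries labelled Tet3 KO and by -1.06 with siTet3-1 and -1.14 with siTet3-2. In MCF7 TET3 changed by 0.265 in the libraries labelled TET3 KO and by -1.41 with shTET3-1 and -1.92 with shTET3-2, also not tested.

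Pigment lineage genes in B16F10 had a median of -1.01 in the libraries labelled Tet3 KO and 0.75 with siTet3-2, a difference between tables that was not tested, and neither list call held with an estimated correlation (camera adjusted p = 0.111 and 0.305). Scaling is argued against, since rescaling left medians of -1.06 and 0.641. A different depth of depletion by the siRNAs is argued against as the cause of their difference, since Tet3 differed by -0.0801 on the log2 scale (SE 0.0482). The list's median difference between siRNAs was 0.649 (camera adjusted p = 3.5e-07, 0.195 with an estimated correlation), and an off-target effect of either siRNA cannot be told apart from a Tet3 effect without a further reagent. A clone difference in the libraries labelled Tet3 KO was not tested.

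By a test of the difference itself, 5103 genes differed between the hairpins and 7562 between the siRNAs. With shTET3-2 minus shTET3-1, the camera test at the preset correlation separated interferon-stimulated genes (median log2 difference 0.189), MHC class I antigen presentation (0.325), NF-kB response (0.236), p53 targets (0.122), hypoxia and glycolysis (0.199), ribosomal proteins (-0.133) and replication-dependent histone genes (-0.267). With siTet3-2 minus siTet3-1 it separated interferon-stimulated genes (0.516), chemokines and immune checkpoint ligands (-0.0221), NF-kB response (-0.719), the stress and unfolded protein response (-0.0863), cholesterol synthesis (-0.215), hypoxia and glycolysis (-0.219), pigment lineage (0.649), mesenchymal transition (-0.242) and ribosomal proteins (0.246). None passed with an estimated correlation, as given above.

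Other lists had medians of opposite sign between tables, differences that were not tested, and none of their calls held with an estimated correlation. The mesenchymal transition list had a median of 0.169 in the MCF7 libraries labelled TET3 KO and -0.298 with shTET3-1 (camera adjusted p with an estimated correlation 0.246 and 0.376), but 0.236 with shTET3-2. For p53 target genes the medians were -0.215 in the libraries labelled TET3 KO, where 1 of 25 fell and 24 did not pass, and 0.276 with shTET3-2 (0.367 and 0.18). In B16F10 the hypoxia and glycolysis list had a median of 0.485 in the libraries labelled Tet3 KO and -0.189 with siTet3-2 (0.424 and 0.14).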

How the results depend on the processing

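Alternatives added after the data were seen are named above, and the others were planned. The rise of the interferon-stimulated list, tested by camera with the preset correlation, kept its direction and its side of the threshold in 40 of 40 values under other processing and 32 of 32 with a library left out, over the 6 comparisons. The calls lost with an estimated correlation are given above. The list's median ranged from 0.63 to 1.08 in the libraries labelled TET3 KO, 0.79 to 1.51 with shTET3-1, 0.96 to 1.71 with shTET3-2, 1.26 to 2.12 in the libraries labelled Tet3 KO, 0.65 to 1.42 with siTet3-1 and 0.94 to 1.88 with siTet3-2. Each TET3 result kept its side as well, with log2 fold changes from 0.20 to 0.33 in the libraries labelled TET3 KO, -1.71 to -1.38 with shTET3-1, -2.47 to -1.89 with shTET3-2, 0.92 to 1.11 in the libraries labelled Tet3 KO, -1.18 to -1.02 with siTet3-1 and -1.27 to -1.11 with siTet3-2. Of the counts of genes past the threshold, 84 of 87 under other processing and 87 of 96 with a library left out stayed within 1.5 times the reported count.

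The exceptions all involved MCF7. With libraries labelled TET3 KO, 238 genes became 48 of 16787 tested without the filter on low values, 24 of them among the 238, and leaving out a library gave 62 (without wild-type replicate 2) to 253 (without TET3 KO replicate 2), with 115 without TET3 KO replicate 1. The 1743 genes called with both hairpins became 1153 to 1551 with a library left out, the lowest without shscramble replicate 2. The 47 genes shared by the libraries labelled TET3 KO and both hairpins became 7 without the filter on low values and 18 to 61 with a library left out (18 without wild-type replicate 2, 24 without wild-type replicate 1 and 28 without TET3 KO replicate 1). The 14 symbols higher in all 6 comparisons became 3 without the filter on low values, 5 without wild-type replicate 2, 7 without wild-type replicate 1 and 9 without TET3 KO replicate 1, and 12 to 14 under the other alternatives. The cause was not tested, except that a fit with a library left out rests on fewer libraries.

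Of the gene list tests, 43 of 95 kept their side of the threshold with an estimated correlation and 52 lost their call. Of the named genes' values under other processing, 2788 were on the same side, 65 lost their call, 4 gained one and 1 reversed: Rplp0 with siTet3-2 went from 0.089 to -0.021 after rescaling (limma adjusted p = 0.445, and at most 0.0772 under its other alternatives). That reversal follows from the shift of all genes that rescaling removes. With a library left out, 2209 were on the same side, 97 lost their call and 2 gained one. Of the lost calls of both kinds together, 79 were in the MCF7 comparison with libraries labelled TET3 KO.

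Libraries with the same replicate number deviated together in the hairpin table and share only a number elsewhere. The correlation across genes of the differences between replicates was 0.136 to 0.237 in the hairpin table, -0.0134 to 0.0369 in the siRNA table, 0.00749 in the MCF7 table with libraries labelled TET3 KO and -0.0115 in the B16F10 table with libraries labelled Tet3 KO. With a replicate block, the counts were 179, 4940, 6034, 8265, 6901 and 7474 genes for libraries labelled TET3 KO, shTET3-1, shTET3-2, libraries labelled Tet3 KO, siTet3-1 and siTet3-2. With that block TET2 with shTET3-1 gained a call (limma adjusted p = 0.0402), and the TET2, IRF7, DDIT4 and TFF3 calls in the libraries labelled TET3 KO were lost (0.161, 0.0665, 0.0635 and 0.16). In the hairpin table camera with the block did not call mesenchymal transition with shTET3-1 and called interferons, receptors and sensing between hairpins (values above). Apart from these and the interferon-stimulated calls above, the block changed no call of a named gene or list test in that table.

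The interferon genes IFNB1, IFNL1, IFNL2 and IFNL3 held few reads and were under the expression filter. In simulations 4.41% of changes of 0.5 were recovered in the MCF7 comparison with libraries labelled TET3 KO, against 100% in the B16F10 comparison with libraries labelled Tet3 KO, which has as many libraries and fewer reads.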

Other observations

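The observations in this part were chosen after the data were seen, and no explanation was tested for them.

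Transcripts of interferon genes themselves were scarce. Reads recovered for IFNL1, a type III interferon, numbered 9 over both shscramble libraries, 67 with shTET3-1 and 42 with shTET3-2, and 8 in wild type against 27 in the MCF7 libraries labelled TET3 KO. IFNB1 had 1 read with shscramble, 14 with shTET3-1 and 10 with shTET3-2, and in wild type 1 and 0 against 0 and 4 in the libraries labelled TET3 KO, which overlap. IFNL2 and IFNL3 are near-identical copies whose reads cannot be assigned to either, and their reads were 1 and 3 with shscramble, 13 and 14 with shTET3-1, 8 and 31 with shTET3-2. They were 10 and 6 in wild type against 19 and 17 in the libraries labelled TET3 KO, where those of IFNL2 overlapped (7 and 3 against 5 and 14). In B16F10 Ifnl2, Ifnl3 and Ifnb1 were at 0 in every library, except Ifnb1 in 1 library labelled Tet3 KO (0.0455 FPKM). These genes were under the expression filter, and no test was made of them.

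Across the members of the interferon-stimulated list, which are not independent replicates, Pearson's r between log2 fold changes was 0.787 for the libraries labelled TET3 KO and shTET3-1 and 0.791 for shTET3-2 (Spearman's rho 0.702 and 0.649, 48 members). In B16F10 it was 0.654 for siTet3-1 and 0.294 for siTet3-2 (rho 0.699 and 0.312, 45 members). Differences between these correlations were not tested.

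Replicates lay further apart in the MCF7 table with libraries labelled TET3 KO than elsewhere. The SD of the log2 difference between the libraries of a group was 0.379 in wild type and 0.432 in libraries labelled TET3 KO, against 0.0841 to 0.102 in the other 8 groups.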
